A study of Mus musculus with 18 samples.

How the data were processed

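RNA was measured by sequencing in 18 libraries from bulk liver and from epithelial fractions of the small and large intestine, taken on day 7 from recipients aged 6 to 8 weeks. Per the labels' protocols, 500 ng of total RNA with integrity numbers of 7.2 to 10 went through polyA selection and a stranded mRNA library kit with 8 PCR cycles, and was read as 100 bp pairs at a mean of 30000000 pairs per sample. Ribosomal reads were 0.2 to 0.9% of the total and mRNA bases averaged 93%, per the labels' protocols. The authors deposited whole-number counts per gene, not normalized, in 1 table of all 18 libraries with 53379 genes. FastQC 0.11.9, STAR 2.7.0e, featureCounts 1.6.3 and the build GRCm38.p5 are named per the submitters' processing notes, while the annotation release and the strand setting of the counting are not given in the sources used here. Reads of genes with close copies or on opposite strands can therefore have been lost or shared in ways that change single-gene counts, and reads from BALB/c mice were aligned to a C57BL/6J reference, which can lower counts of divergent genes such as those of the H2 complex. The strain of the marrow and T cell donors is not given in the sources used here. Fractions of epithelium were counted as collected, so that transcripts of other cells in a fraction enter its counts.

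Groups followed the sample titles. The titles and the library codes of the intestinal sets disagree, so these libraries are called titled small intestine (code LI) and titled large intestine (code SI) throughout. Library depth ran from 18845483 to 25610937 counts, and mitochondrial transcripts took 2.77 to 10.7% of counts, less in each BMT library than in any BM library of the same tissue. Gene names were matched for 53274 of the IDs through a GENCODE release 21 mouse table, and 0.00257% of counts lay in unmatched IDs, which kept their IDs. No pair of replicates was a duplicate, with chi-square per degree of freedom of 9.86 to 187. The labels do not state that the replicates are separate animals, though the library descriptions carry separate numbers, so p-values measure the spread between these samples. Where the mouse number links tissues, deviations from the group means correlated at -0.09 to 0.26 between libraries of the same number, and the pairing rests on the descriptions. Lane numbers, read from the column names, placed 4 libraries on lane L001.

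Each tissue was fitted separately with edgeR 4.0.16 in R 4.3.3, using its expression filter by group, TMM scaling and the two-sided quasi-likelihood F-test, with calls at a Benjamini-Hochberg adjusted p of 0.05. The standard error of a log2 fold change is its size over the square root of F. Gene lists (38, with 666 genes, of which 1 was unmatched and 2 were renamed by synonym) were fixed before the data were examined, and those with at least 5 tested members were tested with camera of limma 3.58.1 on log-CPM values with a preset inter-gene correlation of 0.01. Between 26 and 31 lists were tested per tissue and adjusted together, and counts over the list alone use the same p-values adjusted within the list. With an estimated correlation none of the 42 list calls held, and that adjusted p stands beside each. That setting changes more in camera than the correlation. Differences of the BMT effect between tissues were fitted in 1 edgeR model over 18 libraries with tissue, treatment within tissue and mouse, since the descriptions repeat the same 6 numbers in every tissue. Region identity was compared per mouse with an exact sign-flip permutation test on log2(CPM + 1).

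The genes named were chosen by a rule fixed before the data were examined. It took, per tissue, the 5 largest rises and 5 largest falls among calls with a mean of at least 5 CPM and no overlap of the groups (10% of genes would show none by chance with 3 against 3), without unnamed gene models and receptor segments, then 2 members with the smallest p of each called list, a set of bile acid genes whatever their result, and 4 genes per tissue contrast. Some of these genes are not reported here. Members named in parentheses because a count was 5 or fewer, the region markers given with values, and Alb were chosen after their values were seen. A fold against a group at 0 was computed against 3 counts over the group, and ratios with 1 to 3 counts carry a 95% interval.

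The scripts were tested on simulated counts with 200 changed genes. Of genes changed 2-fold and 4-fold, 28.4% and 89.4% were recovered among 14134 liver genes, 61.2% and 90.9% among 14880 of the libraries titled small intestine, and 49.3% and 84.8% among 14621 of those titled large intestine, with 8, 6 and 8 false calls. Of genes changed 1.5-fold, 2.99, 7.46 and 5.97% were recovered. Of 2-fold and 4-fold differences between tissues, 14 and 61% (liver and titled large intestine, 8 false calls of 83) and 18 and 57% (both intestinal sets, 6 false calls of 81) were recovered among 17275 genes, so most simulated 2-fold differences between tissues were missed. The real comparisons called more genes than were changed here, 1528 to 6157 per tissue and 848 to 3242 per contrast. More true changes loosen the Benjamini-Hochberg cut-off, so recovery in the real data may differ from all these shares. The contrast of liver with titled small intestine, simulated without a change, gave 0 calls. Alternatives fixed before the data were examined were DESeq2 size factors, no low-count filter, a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, 1 fit of all 18 libraries, a replicate block, a 2-fold threshold, an estimated correlation and fry for lists, no mouse block, only the libraries of both tissues, other identity scores, and leaving out each library or mouse. Lane as a covariate, lane L002 alone and the list tests of tissue differences were chosen after seeing the data, as were their settings: members above the filter in both tissues, or in any 1 tissue, and hepatocyte markers without mouse 10. No sample was left out of the main comparisons. A range of adjusted p over filtered alternatives leaves out the setting without a low-count filter, a choice made after its values were seen. Without that filter edgeR's prior degrees of freedom rose from 3.8 to 14.5 in liver, and from 6.42 and 7.06 to infinity in titled small and titled large intestine, so that the spread of single genes weighed less in liver and no longer entered the test in the intestinal sets.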

Results

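Gene counts were analysed from 18 RNA-seq libraries of female BALB/cJ mice (a common inbred strain), lethally irradiated and transplanted with 10000000 bone marrow cells alone (BM) or together with 1000000 T cells (BMT). Tissue was taken on day 7. RNA came from bulk liver and from epithelium isolated from both parts of the intestine, with 3 libraries per treatment in each of the 3 tissues. The library descriptions carry the same 6 numbers in each tissue, read here as 6 mice. The series title names microbial bile acid metabolism and effector T cells, so bile acid genes are given whatever their result. Each library held between 18845483 and 25610937 counts, so that the floor of 3 counts stood between 0.117 and 0.159 CPM (counts scaled to library size, in the usual unit). Counting intervals and floors cover counting error only. Each ± on a log2 fold change is a standard error and each ± on CPM a standard deviation, with n = 3 per group. Fold changes are BMT over BM, and unless another test is named, adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Camera tests a list against the other genes and fry tests it against no change, so their p-values answer different questions. List medians are of log2 fold changes, and counts over the list alone use p adjusted within the list. Gene positions are on GRCm38.

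The labels of the intestinal libraries were in conflict, so region markers were examined first. The 6 libraries titled small intestine carry the code LI in their descriptions, and the 6 titled large intestine carry SI. Genes of the distal bowel were higher in the libraries titled small intestine (library code LI) than in those titled large intestine (code SI). Hoxb13, a homeobox gene of the posterior body, stood at 132 ± 49.6 CPM against 0 counts in all 6 of the other set, and Car1 and Aqp8 at 7879 ± 2216 and 178 ± 217 CPM, and 422 ± 153 and 1.14 ± 2.06 CPM, respectively (n = 6). Genes of the small intestine ran the other way, with the Paneth cell lysozyme Lyz1 at 1.17 ± 1.95 and 3577 ± 3020.5 CPM, the ileal bile acid binding protein gene Fabp6 at 4.34 ± 4.14 and 5539.9 ± 3237 CPM and sucrase-isomaltase (Sis) at 1.68 ± 1.05 and 1467 ± 805 CPM. Of 18 large intestine genes, 15 were higher in all 6 libraries titled small intestine, and of 20 small intestine genes, 18 were higher in all 6 titled large intestine. The difference of the list means (small minus large intestine list, log2(CPM + 1)), titled small minus titled large, was -9.48 ± 0.64 (SD, 6 mice; exact two-sided sign-flip permutation p = 0.03125, the smallest that 6 mice allow). The region markers ran against the titles, and every direction below is given for libraries as titled, with their code.

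**Figure D1:**
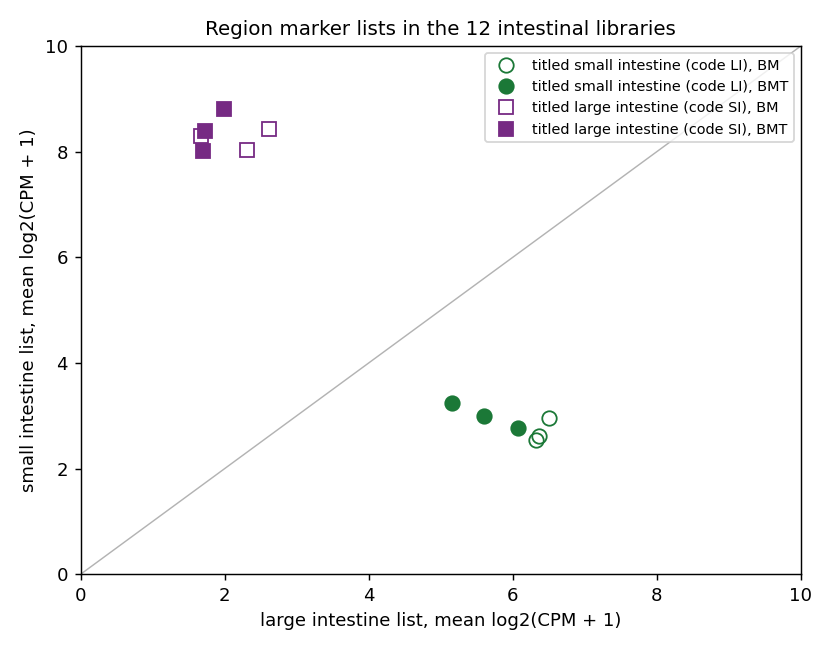
Mean log2(CPM + 1) of the large intestine list (x axis) against that of the small intestine list (y axis), 1 point per library, with circles for libraries titled small intestine (code LI), squares for those titled large intestine (code SI), open symbols for BM and filled ones for BMT. All 6 circles lie below the diagonal and all 6 squares above it.

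The comparison of BMT with BM in bulk liver asked how the liver transcriptome differed once T cells were given with the marrow. As lists, genes of T cells, neutrophils and acute phase proteins were higher, with 21 of 22, 16 of 16 and 22 of 23 genes called, and drug-metabolising enzymes and erythroid genes lower (11 of 24 and 5 of 7). With an estimated correlation these 5 lists lost their calls (adjusted p = 0.111 to 0.394), and the enzyme list did not pass by fry. The largest rises were in Chil3 (ENSMUSG00000040809.10, chromosome 3, 106147554 to 106167564), a chitinase-like protein of myeloid cells (7.28 ± 0.88, adjusted p = 0.00326), the scavenger receptor gene Scara5 (6.92 ± 1.04, adjusted p = 0.00703), the serum amyloid genes Saa2 (6.65 ± 0.69, adjusted p = 0.00222) and Saa1 (6.09 ± 0.65, adjusted p = 0.00233), and the neutrophil surface gene Cd177 (6.09 ± 0.77, adjusted p = 0.00379). Saa1 went from 122 ± 82.2 CPM in BM to 8347 ± 656 CPM in BMT. The largest falls were in the desaturase gene Scd1 (-5.45 ± 1.26, adjusted p = 0.032), the major urinary protein gene Mup3 (-4.99 ± 0.65, adjusted p = 0.0042), carbonic anhydrase 3 (Car3, -4.79 ± 0.51, adjusted p = 0.00232), Cyp2c69 (-4.56 ± 0.58, adjusted p = 0.00391) and the carboxylesterase gene Ces1f (ENSMUSG00000031725.8, chromosome 8, 93256236 to 93279747; -4.53 ± 0.42, adjusted p = 0.00183). Scd1 lost its call without BM replicate 2 (adjusted p = 0.0804) or BMT replicate 1 (adjusted p = 0.104, 0.000127 to 0.104 over its filtered alternatives). Saa, Mup, Ces1 and Cyp2c genes have near-identical copies, so their single-gene counts are uncertain.

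Of 22 T cell genes tested, 21 rose and 0 fell, against 21 and 0 over the list alone. The T cell list had a median of 3.66, with camera adjusted p = 1.15e-22 and adjusted p = 0.111 with an estimated correlation. The surface gene Thy1 went from 1.16 ± 0.12 CPM in BM to 15 ± 1.05 CPM in BMT (3.69 ± 0.17, adjusted p = 0.00046), and the receptor constant gene Trbc2 had a log2 fold change of 3.59 ± 0.25, adjusted p = 0.00122. Of 21 cytotoxic and effector T cell genes tested, 20 rose and 0 fell, against 21 and 0 over the list alone. The cytotoxic and effector T cell list had a median of 3.26, with camera adjusted p = 4.04e-19 and adjusted p = 0.201 with an estimated correlation. Perforin (Prf1) rose by 3.11 ± 0.28 on the log2 scale (adjusted p = 0.00174) and the inhibitory receptor gene Tigit by 4.72 ± 0.45 (adjusted p = 0.00183). Of 16 neutrophil genes tested, 16 rose and 0 fell, against 16 and 0 over the list alone. The neutrophil list had a median of 4.35, with camera adjusted p = 1.18e-14 and adjusted p = 0.291 with an estimated correlation. The granule protease gene Prtn3 went from 0.27 ± 0.122 CPM in BM to 18.4 ± 6.11 CPM in BMT (6.05 ± 0.41, adjusted p = 0.00118), and myeloperoxidase (Mpo) rose by 5.24 ± 0.61 (adjusted p = 0.00306). Of 18 monocyte and macrophage genes tested, 7 rose and 0 fell, against 7 and 0 over the list alone. The monocyte and macrophage list had a median of 0.57, with camera adjusted p = 1.33e-05 and adjusted p = 0.394 with an estimated correlation. Cd14, a lipopolysaccharide co-receptor, rose by 3.28 ± 0.29 (adjusted p = 0.00174) and Ly6c2, of inflammatory monocytes, by 4.23 ± 0.51 (adjusted p = 0.00326). Of 24 cell cycle genes tested, 15 rose and 0 fell, against 21 and 0 over the list alone. The cell cycle list had a median of 1.85, with camera adjusted p = 9.36e-13 and adjusted p = 0.201 with an estimated correlation. Mki67 and Top2a, of dividing cells, rose by 2.69 ± 0.23 and 2.27 ± 0.21.

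Of 23 acute phase genes tested, 22 rose and 0 fell, against 22 and 0 over the list alone. The acute phase list had a median of 2.12, with camera adjusted p = 4.04e-19 and adjusted p = 0.111 with an estimated correlation. Metallothionein 1 (Mt1) went from 278 ± 38.9 CPM in BM to 1413 ± 220.1 CPM in BMT (2.35 ± 0.20, adjusted p = 0.00153), and the lipopolysaccharide binding protein gene Lbp rose by 2.11 ± 0.19 (adjusted p = 0.00174). Of 22 cholesterol synthesis genes tested, 8 rose and 0 fell, against 13 and 1 over the list alone. The cholesterol synthesis list had a median of 0.87, with camera adjusted p = 1.16e-05 and adjusted p = 0.394 with an estimated correlation. Srebf2, the transcription factor of this pathway, rose by 1.00 ± 0.13 (adjusted p = 0.00436) and the farnesyl diphosphate synthase gene Fdps by 1.17 ± 0.17 (adjusted p = 0.00631). Of 5 B and plasma cell genes tested, 1 rose (Cd22) and 0 fell, against 2 and 0 over the list alone. The B and plasma cell list had a median of 0.85, with camera adjusted p = 0.0338 (0.0987 without a low-count filter) and adjusted p = 0.332 with an estimated correlation. Cd22 rose by 2.14 ± 0.42 (adjusted p = 0.0174, but 0.0797 without BMT replicate 2 and 0.0636 without BMT replicate 3, 0.000438 to 0.0839 over its filtered alternatives), and Ighm was at 0.85 ± 0.22, adjusted p = 0.0501, 0.0111 to 0.17 over its filtered alternatives. The list's call ended without BM replicate 3 (adjusted p = 0.119) or BMT replicate 2 (adjusted p = 0.0532). Of 20 unfolded protein response genes tested, 1 rose (Asns) and 0 fell, against 1 and 0 over the list alone. The unfolded protein response list had a median of 0.28, with camera adjusted p = 0.0421 (0.0811 by fry) and adjusted p = 0.394 with an estimated correlation. Asparagine synthetase (Asns) had 3.01 ± 0.66, adjusted p = 0.0271, a call lost without any of 4 libraries (BM replicates 1 and 2, BMT replicates 1 and 2; adjusted p = 0.0578 to 0.105, 0.000628 to 0.105 over its filtered alternatives), and Pdia4 was at 0.52 ± 0.15, adjusted p = 0.0636, 0.0129 to 0.235 over its filtered alternatives. Its list lost its call without BM replicate 1 or 2 or BMT replicate 2 or 3 (adjusted p = 0.0539 to 0.145).

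Of 24 xenobiotic P450 and conjugation genes tested, 0 rose and 11 fell, against 1 and 12 over the list alone. The xenobiotic P450 and conjugation list had a median of -1.02, with camera adjusted p = 5.44e-06 (0.0689 by fry) and adjusted p = 0.394 with an estimated correlation. Cyp1a2, an enzyme of drug oxidation, went from 486 ± 67.8 CPM in BM to 108 ± 47.2 CPM in BMT (-2.17 ± 0.33, adjusted p = 0.00717), and the glutathione transferase gene Gstm1 had a log2 fold change of -1.85 ± 0.28, adjusted p = 0.00731. Of 7 erythroid genes tested, 0 rose and 5 fell (Hba-a1, Hba-a2, Hbb-bs, Hbb-bt, Slc4a1), against 0 and 5 over the list alone. The erythroid list had a median of -2.24, with camera adjusted p = 0.000153 and adjusted p = 0.35 with an estimated correlation. The globin genes Hbb-bt (-3.00 ± 0.43, adjusted p = 0.00575) and Hba-a1 (-2.14 ± 0.39, adjusted p = 0.0138) were the named members, the latter with a near-identical copy and without a call when BMT replicate 2 was left out (adjusted p = 0.0741, 1.73e-06 to 0.0741 over its filtered alternatives). Of 20 p53 target genes tested, 0 rose and 5 fell (Ccng1, Phlda3, Eda2r, Aen, Ddit4l), against 3 and 6 over the list alone. The p53 target list had a median of -0.58, with camera adjusted p = 0.0437 (0.247 by fry) and adjusted p = 0.618 with an estimated correlation. Eda2r (-1.63 ± 0.27, adjusted p = 0.00931), a receptor of the tumour necrosis factor family, and Ddit4l (-2.17 ± 0.37, adjusted p = 0.0112, but 0.0521 on lane L002 alone, 4.37e-06 to 0.0521 over its filtered alternatives), a stress-response gene, fell. The p53 list lost its call without BM replicate 1, BMT replicate 1 or BMT replicate 3 (adjusted p = 0.0517 to 0.242), and with the replicate block (adjusted p = 0.0556).

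The results of the interferon and antigen presentation lists depended on which BM livers were kept. Of 24 type I interferon response genes tested, 0 rose and 1 fell (Rsad2), against 0 and 1 over the list alone. The type I interferon response list had a median of -0.64, with camera adjusted p = 0.0289 (0.593 by fry) and adjusted p = 0.786 with an estimated correlation. Rsad2, an antiviral gene, had a log2 fold change of -1.71 ± 0.24, adjusted p = 0.00575, and Cmpk2 one of -0.98 ± 0.30, adjusted p = 0.0773, 0.00495 to 0.229 over its filtered alternatives. The call of this list ended without BM replicate 3 (adjusted p = 0.719) or BMT replicate 1 (adjusted p = 0.139). Interferon gamma response genes gave no list call (median -0.54, adjusted p = 0.693). Of 29 tested, 0 rose and 0 fell (0 and 0 over the list alone). Without BM replicate 3 that list was higher in BMT (adjusted p = 0.0244), and without BM replicate 1 it was lower (adjusted p = 6.77e-05). MHC class I genes gave no list call (median -0.16, adjusted p = 0.956). Of 20 tested, 0 rose and 0 fell (0 and 0 over the list alone). Leaving out BM replicate 1 gave this list adjusted p = 0.00585, lower in BMT. Of 9 MHC class II genes tested, 1 rose (Ctss) and 0 fell, against 1 and 0 over the list alone. The MHC class II list had a median of 0.71, with camera adjusted p = 0.0231 (0.287 by fry) and adjusted p = 0.618 with an estimated correlation. The protease gene Ctss had 1.38 ± 0.21, adjusted p = 0.00682, and the invariant chain gene Cd74 had 1.31 ± 0.89, adjusted p = 0.397, or 3.38 with adjusted p = 0.00182 without BM replicate 3 (adjusted p 0.00182 to 0.656 over its filtered alternatives). The class II list lost its call without BM replicate 1 or 2 or BMT replicate 3 (adjusted p = 0.0517 to 0.15).

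None of the 3 bile acid lists was called in the 6 livers together. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 129 ± 101 CPM in BM and 127 ± 81.1 CPM in BMT (-0.02 ± 0.85, adjusted p = 0.991), with BM libraries at 12.8, 197 and 176 CPM. A difference was not detectable with this spread between libraries. Cyp7b1, of the alternative pathway, fell from 26 ± 9.77 CPM in BM to 8.29 ± 1.63 CPM in BMT (-1.65 ± 0.28, adjusted p = 0.0101), a call lost without BMT replicate 2 (adjusted p = 0.0579, 1.31e-06 to 0.0579 over its filtered alternatives). No call was made for Cyp8b1 (0.76 ± 0.40, adjusted p = 0.275), Cyp27a1 (0.18 ± 0.22, adjusted p = 0.644), the uptake transporter gene Slc10a1 (0.24 ± 0.22, adjusted p = 0.55), the receptor gene Nr1h4 (0.41 ± 0.20, adjusted p = 0.253) or its target Nr0b2 (-0.61 ± 0.43, adjusted p = 0.418, or adjusted p = 0.0224 with the replicate block, 0.0224 to 0.866 over its filtered alternatives). The bile salt export pump gene Abcb11 (-0.51 ± 0.32, adjusted p = 0.361) passed without BM replicate 3 (adjusted p = 0.025, 0.025 to 0.757 over its filtered alternatives). Bile acid synthesis genes gave no list call (median -0.10, mean 0.01, adjusted p = 0.914). Of 16 tested, 2 rose (Cyp39a1, Acox2) and 1 fell (Cyp7b1) (2 and 1 over the list alone). Bile acid transport genes gave no list call (median -0.45, adjusted p = 0.0662, but 0.028 without a low-count filter, 0.00884 without BM replicate 3 and 0.0224 without BMT replicate 1). Of 14 tested, 0 rose and 2 fell (Slco1a4, Abcg8) (0 and 2 over the list alone). Bile acid sensing genes gave no list call (median 0.14, adjusted p = 0.432). Of 13 tested, 2 rose (Fgfr4, Vdr) and 0 fell (2 and 0 over the list alone).

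Other liver lists gave no call. PPAR alpha and fatty acid oxidation genes gave no list call (median -0.18, adjusted p = 0.138, but 0.0184 without BM replicate 3 and 0.0101 without BMT replicate 2). Of 21 tested, 1 rose (Vnn1) and 2 fell (Ehhadh, Acaa1b) (1 and 3 over the list alone). Leukocyte chemokine genes gave no list call (median -0.07, mean 0.17, adjusted p = 0.571, unlike the test's direction, higher). Of 7 tested, 1 rose (Cxcl1) and 0 fell (2 and 0 over the list alone). Kupffer cell genes gave no list call (median 0.19, adjusted p = 0.195). Of 10 tested, 1 rose (Cd163) and 0 fell (1 and 0 over the list alone). Endothelial genes gave no list call (median 0.53, adjusted p = 0.0551, but 0.0409 without BM replicate 1, 0.0275 without BM replicate 3 and 0.0317 without BMT replicate 1). Of 16 tested, 3 rose (Pecam1, Eng, Stab2) and 0 fell (5 and 0 over the list alone). Fibroblast and stellate cell genes gave no list call (median 0.21, adjusted p = 0.06, but 0.00209 without BM replicate 1 and 0.0432 without BMT replicate 2). Of 14 tested, 4 rose (Col1a1, Col1a2, Col6a1, Pdgfra) and 0 fell (5 and 0 over the list alone). Hepatocyte marker genes gave no list call (median 0.09, adjusted p = 0.914). Of 20 tested, 3 rose (Apoa1, Serpina1c, Ambp) and 2 fell (Apoa2, Gys2) (5 and 5 over the list alone). Cholangiocyte genes gave no list call (median 0.29, mean -0.05, adjusted p = 0.571). Of 8 tested, 1 rose and 1 fell (Prom1) (2 and 1 over the list alone).

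In liver, of 14134 genes tested, 1055 were higher and 473 lower in BMT (836 and 197 by at least 2-fold), and 10 of 26 lists were higher and 4 lower. Higher genes numbered 519, 554 and 459 without BM replicate 2, BMT replicate 1 and BMT replicate 2. Lower genes numbered 162, 1061, 178, 110 and 232 without BM replicates 2 and 3 and BMT replicates 1, 2 and 3. The liver libraries ran on 2 lanes, with 1 BM and 1 BMT library on lane L001. Lane as a covariate gave 963 higher and 422 lower genes, and lane L002 alone (2 libraries against 2) gave 857 and 378; both settings were chosen after seeing the data. Mitochondrial transcripts took 4.22 to 5.26% of counts in BM and 2.77 to 3.08% in BMT livers.

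In the epithelial libraries titled small intestine (library code LI), the same comparison asked what the added T cells changed in the intestine. As lists, T cell (23 of 24 genes called higher), interferon gamma (29 of 30), class I (18 of 20) and class II genes (9 of 10) were higher, and bile acid synthesis genes (7 of 9) lower. With an estimated correlation these 5 lists lost their calls (adjusted p = 0.306 to 0.315). Among the largest rises, Cd5 (ENSMUSG00000024669.7, chromosome 19, 10718143 to 10738974), a T cell surface gene, and S1pr1, a receptor of lymphocyte traffic, had 0 counts in the 3 BM libraries together, and were at least 303-fold and at least 278-fold higher in BMT against a floor of 3 counts over the group (13.4 ± 3.29 and 12.3 ± 4.89 CPM). With 1 to 3 counts in BM, Cd4 had a ratio of 1651 (95% counting interval 457 to 13635), the checkpoint receptor gene Pdcd1 a ratio of 1221 (95% counting interval 338 to 10092) and Chil3 a ratio of 1497 (95% counting interval 268 to 59156). All 5 passed the test (adjusted p = 8.19e-08 to 0.000508). The largest falls were in the carboxylesterase genes Ces1d and Ces1g, the sulfotransferase gene Sult1c2 and the cytochromes Cyp2f2 and Cyp4b1. Ces1g (ENSMUSG00000057074.6, chromosome 8, 93302369 to 93337308) went from 172 ± 24.1 CPM in BM to 0.143 ± 0.106 CPM in BMT (-10.23 ± 0.30, adjusted p = 3.28e-08), Cyp2f2 fell by 8.05 ± 0.42 (adjusted p = 3.05e-07) and Cyp4b1 fell by 8.04 ± 0.38 (adjusted p = 1.84e-07). With 3 counts in BMT, Ces1d had a ratio of 1768 (95% counting interval 605 to 8575), BM over BMT, and Sult1c2 a ratio of 597 (95% counting interval 204 to 2898).

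Of 24 T cell genes tested, 23 rose and 0 fell, against 23 and 0 over the list alone. The T cell list had a median of 6.61 (6.51 with genes at 0 in BM set to their bound), with camera adjusted p = 1.12e-18 and adjusted p = 0.306 with an estimated correlation. Thy1 went from 0.455 ± 0.163 CPM in BM to 100.2 ± 17.2 CPM in BMT (7.80 ± 0.26, adjusted p = 4.31e-08). Of 24 cytotoxic and effector T cell genes tested, 24 rose and 0 fell, against 24 and 0 over the list alone. The cytotoxic and effector T cell list had a median of 7.49 (7.40 with genes at 0 in BM set to their bound), with camera adjusted p = 1.68e-20 and adjusted p = 0.306 with an estimated correlation. The granzyme genes Gzma and Gzmb rose by 9.53 ± 0.32 and 7.76 ± 0.27 on the log2 scale, Gzmb from 0.901 ± 0.376 CPM in BM to 194 ± 32.1 CPM in BMT. Of 15 monocyte and macrophage genes tested, 13 rose and 1 fell (C1qa), against 13 and 1 over the list alone. The monocyte and macrophage list had a median of 2.74, with camera adjusted p = 7.2e-05 (0.306 with an estimated correlation). Ly6c2 rose by 4.70 ± 0.25 and the chemokine receptor gene Ccr2 by 6.03 ± 0.41. Of 16 fixed neutrophil genes only 6 were above the count filter, and these 6 rose, also over the list alone. The neutrophil list had a median of 4.32, with camera adjusted p = 0.000937 (0.306 with an estimated correlation). Ly6g went from 74.8 ± 4.82 CPM in BM to 1033 ± 362 CPM in BMT (3.79 ± 0.26, adjusted p = 1.77e-06), and the lactoferrin gene Ltf from 0.571 ± 0.192 to 3.01 ± 0.807 CPM. Ly6 genes have close copies, and a neutrophil source of Ly6g was not shown.

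Of 30 interferon gamma response genes tested, 29 rose and 0 fell, against 29 and 0 over the list alone. The interferon gamma response list had a median of 2.21, with camera adjusted p = 2.16e-13 and adjusted p = 0.306 with an estimated correlation. Nlrc5, the activator of class I genes, rose by 2.48 ± 0.14 (adjusted p = 4.7e-07) and the ubiquitin-like gene Ubd by 4.74 ± 0.30 (adjusted p = 1.02e-06). Of 24 type I interferon response genes tested, 21 rose and 0 fell, against 22 and 0 over the list alone. The type I interferon response list had a median of 2.02, with camera adjusted p = 6.91e-10 and adjusted p = 0.315 with an estimated correlation. Usp18 and Rsad2 rose by 3.68 ± 0.24 and 2.83 ± 0.22. Of 20 MHC class I genes tested, 18 rose and 0 fell, against 18 and 0 over the list alone. The MHC class I list had a median of 1.37, with camera adjusted p = 8.39e-09 and adjusted p = 0.315 with an estimated correlation. H2-Q7 and H2-K1 rose by 3.74 ± 0.19 and 2.07 ± 0.15, with counts that near-identical H2 genes and the BALB/c haplotype make uncertain. The strain of the donors is not given in the sources used here, and donor transcripts of another haplotype can align differently to the reference. Of 10 MHC class II genes tested, 9 rose and 0 fell, against 9 and 0 over the list alone. The MHC class II list had a median of 3.05, with camera adjusted p = 4.18e-07 and adjusted p = 0.306 with an estimated correlation. H2-Aa went from 98.7 ± 8.22 CPM in BM to 1086 ± 208 CPM in BMT (3.46 ± 0.18, adjusted p = 2.78e-07), and H2-Eb1 rose by 3.67 ± 0.20. Of 24 cell cycle genes tested, 23 rose and 0 fell, against 23 and 0 over the list alone. The cell cycle list had a median of 1.10, with camera adjusted p = 5.74e-09 and adjusted p = 0.315 with an estimated correlation. Mcm5, of DNA replication, and the mitotic kinase gene Aurka rose by 1.37 ± 0.12 and 1.35 ± 0.13. Of 15 regenerative epithelium genes tested, 10 rose and 2 fell (Ccn1, Mal), against 10 and 2 over the list alone. The regenerative epithelium list had a median of 1.24, with camera adjusted p = 0.00565 and adjusted p = 0.306 with an estimated correlation. Ly6a went from 182 ± 15.6 CPM in BM to 1932 ± 383 CPM in BMT (3.41 ± 0.17, adjusted p = 2.86e-07), and Ly6d rose by 4.31 ± 0.42. T cells also express Ly6a.

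Of 9 bile acid synthesis genes tested, 0 rose and 7 fell, against 0 and 7 over the list alone. The bile acid synthesis list had a median of -1.42, with camera adjusted p = 0.000566 and adjusted p = 0.306 with an estimated correlation. Cyp39a1, an oxysterol hydroxylase, went from 20.2 ± 0.894 CPM in BM to 3.3 ± 0.157 CPM in BMT (-2.61 ± 0.17, adjusted p = 1.15e-06), and Acox2, of side-chain oxidation, fell by 1.84 ± 0.25 (adjusted p = 0.000193). Of 18 PPAR alpha and fatty acid oxidation genes tested, 3 rose (Acadl, Pdk4, Creb3l3) and 9 fell, against 3 and 9 over the list alone. The PPAR alpha and fatty acid oxidation list had a median of -0.31, with camera adjusted p = 0.0325 and adjusted p = 0.306 with an estimated correlation. The transcription factor gene Creb3l3 rose by 3.41 ± 0.23. Of 22 cholesterol synthesis genes tested, 8 rose and 2 fell (Dhcr7, Stard4), against 10 and 3 over the list alone. The cholesterol synthesis list had a median of 0.31, with camera adjusted p = 0.0487 (0.055 by fry) and adjusted p = 0.562 with an estimated correlation. The sterol carrier gene Stard4 fell by 0.86 ± 0.13. With the replicate block the PPAR alpha and cholesterol lists each had adjusted p = 0.0636, and the cholesterol list lost its call without BM replicate 1, BM replicate 2 or BMT replicate 3 (adjusted p = 0.0883 to 0.141). Of the bile acid transporters and receptors, Slc51b, a subunit of the basolateral exporter, went from 32.6 ± 2.2 CPM in BM to 111 ± 8.72 CPM in BMT (1.76 ± 0.13, adjusted p = 2.83e-06). Its partner Slc51a rose by 0.73 ± 0.15 (adjusted p = 0.00308) and Nr1h4 by 0.48 ± 0.14 (adjusted p = 0.0167, but 0.0885 without BM replicate 1, 0.0031 to 0.0885 over its filtered alternatives). Fabp6 was at 7.34 ± 3.94 CPM in BM and 1.36 ± 0.555 CPM in BMT (-2.45 ± 0.41, adjusted p = 0.000932). The uptake transporter gene Slc10a2 had 0.03 ± 0.33, adjusted p = 0.952, and -0.55 with adjusted p = 0.0414 without BMT replicate 1 (adjusted p 0.0414 to 0.994 over its filtered alternatives). Fgf15 and Gpbar1 were below the count filter.

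Lists of the other epithelial and stromal cell types gave no call in these libraries. Bile acid transport genes gave no list call (median -0.35, adjusted p = 0.776). Of 8 tested, 3 rose (Slc51a, Slc51b, Abcc4) and 4 fell (Fabp6, Abcc3, Atp8b1, Abcg5) (3 and 4 over the list alone). Bile acid sensing genes gave no list call (median -0.19, adjusted p = 0.686, and 0.00469 by fry). Of 12 tested, 5 rose (Nr1h4, Fgfr4, Mafg, Sqstm1, S1pr2) and 5 fell (Klb, Nr5a2, Nr1i2, Nr1i3, Vdr) (5 and 5 over the list alone). Intestinal stem cell genes gave no list call (median -0.54, adjusted p = 0.0629, but 0.0219 without a low-count filter, 0.0383 with the replicate block, 0.0276 without BM replicate 2, 0.0479 without BMT replicate 1 and 0.0359 without BMT replicate 2, and 0.00713 by fry). Of 15 tested, 1 rose (Ascl2) and 7 fell (1 and 7 over the list alone). Paneth cell genes gave no list call (median 0.50, adjusted p = 0.134, and 0.000722 by fry). Of 8 tested, 4 rose (Ang4, Mmp7, Itln1, Pla2g2a) and 1 fell (Lyz1) (4 and 1 over the list alone). Goblet cell genes gave no list call (median -0.20, adjusted p = 0.23, but 0.0182 without BMT replicate 3). Of 14 tested, 1 rose (Clca1) and 4 fell (Zg16, Spink4, Klk1, Tspan13) (1 and 4 over the list alone). Enteroendocrine genes gave no list call (median -0.73, adjusted p = 0.0713, but 0.0226 without a low-count filter, 0.0287 without BM replicate 3, 0.03 without BMT replicate 2 and 0.0469 without BMT replicate 3, and 0.0489 by fry). Of 17 tested, 2 rose (Chga, Tph1) and 4 fell (Neurod1, Pax4, Rfx6, Isl1) (2 and 4 over the list alone). Tuft cell genes gave no list call (median 0.91, adjusted p = 0.225, and 0.000277 by fry). Of 7 tested, 3 rose (among them Avil, Spib) and 0 fell (3 and 0 over the list alone). Absorptive enterocyte genes gave no list call (median 0.25, adjusted p = 0.686). Of 18 tested, 7 rose and 5 fell (Sis, Slc2a5, Anpep, Aqp8, Slc26a3) (8 and 6 over the list alone). Epithelial defence genes gave no list call (median -0.07, adjusted p = 0.918). Of 16 tested, 6 rose and 5 fell (Reg3b, Reg3g, Reg4, Pigr, Il18) (6 and 6 over the list alone). Tight junction and adhesion genes gave no list call (median 0.10, mean -0.04, adjusted p = 0.993, unlike the test's direction, lower). Of 19 tested, 3 rose (Cldn4, Cgn, Cdh17) and 4 fell (Cldn8, Cldn12, Cldn15, Marveld2) (3 and 4 over the list alone). Leukocyte chemokine genes gave no list call (median 0.59, adjusted p = 0.0995, but 0.0131 without a low-count filter and 0.0479 without BMT replicate 1, and 0.0188 by fry). Of 12 tested, 6 rose and 2 fell (Ccl28, Cxcl13) (6 and 2 over the list alone). Fibroblast and stellate cell genes gave no list call (median -0.56, adjusted p = 0.359). Of 11 tested, 1 rose (Acta2) and 1 fell (Lrat) (1 and 1 over the list alone). P53 target genes gave no list call (median -0.08, adjusted p = 0.825). Of 19 tested, 4 rose (Bax, Phlda3, Gtse1, Aen) and 4 fell (Trp53inp1, Ccng1, Eda2r, Btg2) (4 and 4 over the list alone). Unfolded protein response genes gave no list call (median 0.15, adjusted p = 0.115, but 0.0359 without BM replicate 3 and 0.0492 without BMT replicate 1). Of 20 tested, 7 rose and 2 fell (Xbp1, Dnajb9) (8 and 2 over the list alone). Hepatocyte marker genes gave no list call (median -1.81, adjusted p = 0.0922, and 0.000131 by fry). Of 11 tested, 3 rose (Apoa1, Ass1, Arg1) and 6 fell (3 and 6 over the list alone).

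For the libraries titled small intestine, of 14880 genes tested, 3033 were higher and 3124 lower in BMT (1592 and 1515 by at least 2-fold), and 11 of 28 lists were higher and 2 lower. Without BMT replicate 2 or BMT replicate 3, 4 lists were lower. BMT replicate 3 was the only library of this set on lane L001, so that lane and treatment could be separated here only by leaving it out, which gave 3667 higher and 3553 lower genes. Mitochondrial transcripts took 9.72 to 10.7% of counts in BM and 6.24 to 7.46% in BMT libraries.

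In the epithelial libraries titled large intestine (code SI), T cell and interferon gamma genes were higher as lists (22 of 24 and 29 of 30 called), and Paneth, stem, goblet and enteroendocrine genes lower (10 of 13, 11 of 15, 7 of 14 and 15 of 17). With an estimated correlation these 6 lists lost their calls (adjusted p = 0.223 to 0.551). With 1 to 3 counts in BM, the T cell adhesion gene Cd2 (ENSMUSG00000027863.8, chromosome 3, 101275899 to 101287939) had a ratio of 749.9 (95% counting interval 134 to 29659), the granzyme gene Gzmk a ratio of 691 (95% counting interval 124 to 27316), Cd8b1 a ratio of 495 (95% counting interval 169 to 2403), Pdcd1 a ratio of 444 (95% counting interval 123 to 3675) and the receptor gene Klrc1 a ratio of 339 (95% counting interval 93.4 to 2803) (adjusted p = 3.99e-06 to 6.66e-06). The largest falls were in Cyp3a25 (ENSMUSG00000029630.15, chromosome 5, 145977194 to 146009618; -5.46 ± 0.50, adjusted p = 3.13e-05), Cyp2c55 (-5.01 ± 0.71, adjusted p = 0.000562), the hydroxyacid oxidase gene Hao2 (-4.70 ± 0.47, adjusted p = 5.44e-05), the Paneth cell defensin gene Defa29 (-4.41 ± 0.31, adjusted p = 8.17e-06) and the phospholipase gene Plb1 (-4.40 ± 0.75, adjusted p = 0.00175).

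Of 24 T cell genes tested, 22 rose and 0 fell, against 22 and 1 over the list alone. The T cell list had a median of 5.34 (5.19 with genes at 0 in BM set to their bound), with camera adjusted p = 2.19e-20 and adjusted p = 0.223 with an estimated correlation. Thy1 went from 0.265 ± 0.0997 CPM in BM to 48.1 ± 9.59 CPM in BMT (7.48 ± 0.31, adjusted p = 7.92e-07). Of 23 cytotoxic and effector T cell genes tested, 23 rose and 0 fell, against 23 and 0 over the list alone. The cytotoxic and effector T cell list had a median of 5.36, with camera adjusted p = 1.16e-24 and adjusted p = 0.223 with an estimated correlation. Cxcr6, of resident T cells, rose by 5.93 ± 0.31 and the granule gene Nkg7 by 5.09 ± 0.28. Of 30 interferon gamma response genes tested, 29 rose and 1 fell (Nos2), against 29 and 1 over the list alone. The interferon gamma response list had a median of 2.60, with camera adjusted p = 1.31e-16 and adjusted p = 0.41 with an estimated correlation. Ubd and the chemokine gene Cxcl11 rose by 3.83 ± 0.23 and 3.34 ± 0.24. Of 24 type I interferon response genes tested, 16 rose and 0 fell, against 19 and 0 over the list alone. The type I interferon response list had a median of 1.17, with camera adjusted p = 4.57e-07 (0.0836 by fry) and adjusted p = 0.481 with an estimated correlation. Usp18 and Ifit2 rose by 3.41 ± 0.39 and 2.57 ± 0.30. Of 20 MHC class I genes tested, 16 rose and 0 fell, against 18 and 0 over the list alone. The MHC class I list had a median of 1.01, with camera adjusted p = 3.1e-09 and adjusted p = 0.436 with an estimated correlation. H2-Q7 and the immunoproteasome gene Psmb8 rose by 3.96 ± 0.26 and 1.66 ± 0.20. Of 9 MHC class II genes tested, 8 rose and 0 fell, against 8 and 0 over the list alone. The MHC class II list had a median of 3.02, with camera adjusted p = 1.44e-07 and adjusted p = 0.436 with an estimated correlation. H2-Eb1 and H2-Aa rose by 3.27 ± 0.27 and 3.06 ± 0.26.

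Of 13 Paneth cell genes tested, 0 rose and 10 fell, against 0 and 11 over the list alone. The Paneth cell list had a median of -1.86, with camera adjusted p = 1.39e-07 and adjusted p = 0.475 with an estimated correlation. Defa29 went from 237 ± 22.5 CPM in BM to 11.1 ± 4.81 CPM in BMT, and Defa26 fell by 3.21 ± 0.27 (adjusted p = 1.73e-05), with counts uncertain among near-identical defensin genes. Of 15 intestinal stem cell genes tested, 0 rose and 11 fell, against 0 and 11 over the list alone. The intestinal stem cell list had a median of -1.05, with camera adjusted p = 9.66e-08 and adjusted p = 0.223 with an estimated correlation. Olfm4 went from 1116 ± 87.8 CPM in BM to 338 ± 52.6 CPM in BMT (-1.72 ± 0.17, adjusted p = 5.4e-05), and the R-spondin receptor gene Lgr5 from 25.3 ± 2.87 CPM in BM to 8.37 ± 0.478 CPM in BMT (-1.59 ± 0.18, adjusted p = 0.000104). Of 17 enteroendocrine genes tested, 0 rose and 15 fell, against 0 and 15 over the list alone. The enteroendocrine list had a median of -1.74, with camera adjusted p = 1.01e-08 and adjusted p = 0.236 with an estimated correlation. The incretin gene Gip fell by 3.99 ± 0.40 (adjusted p = 5.27e-05) and proglucagon (Gcg) by 2.33 ± 0.33 (adjusted p = 0.000605). Of 14 goblet cell genes tested, 0 rose and 7 fell, against 0 and 7 over the list alone. The goblet cell list had a median of -0.43, with camera adjusted p = 0.00416 (0.0906 by fry) and adjusted p = 0.551 with an estimated correlation. Zg16 and Spink4, of goblet cell granules, fell by 1.91 ± 0.26 and 1.79 ± 0.31. Of 5 exocrine pancreas genes tested, 0 rose and 2 fell (among them Clps), against 0 and 3 over the list alone. The exocrine pancreas list had a median of -0.90, with camera adjusted p = 0.0443 (0.169 without a low-count filter; 0.0852 by fry) and adjusted p = 0.481 with an estimated correlation. Clps fell by 1.54 ± 0.40 (adjusted p = 0.0192), but had adjusted p = 0.0798 without BM replicate 1 and 0.0832 without BMT replicate 2 (adjusted p 0.0017 to 0.0832 over its filtered alternatives). The pancreas list lost its call without BMT replicate 1 (adjusted p = 0.136) or BMT replicate 2 (adjusted p = 0.0668).

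Of 21 absorptive enterocyte genes tested, 12 rose and 0 fell, against 15 and 0 over the list alone. The absorptive enterocyte list had a median of 0.83, with camera adjusted p = 5.85e-05 and adjusted p = 0.475 with an estimated correlation. Mttp, of lipoprotein assembly, went from 478 ± 50.7 CPM in BM to 1164 ± 77.7 CPM in BMT (1.28 ± 0.16, adjusted p = 0.000232), and the carbonic anhydrase gene Car4 rose by 2.10 ± 0.26. Of 12 tuft cell genes tested, 9 rose and 0 fell, against 10 and 0 over the list alone. The tuft cell list had a median of 2.51, with camera adjusted p = 5e-06 and adjusted p = 0.475 with an estimated correlation. The taste-pathway channel gene Trpm5 rose by 3.50 ± 0.42. Of 24 cell cycle genes tested, 9 rose and 0 fell, against 13 and 0 over the list alone. The cell cycle list had a median of 0.58, with camera adjusted p = 0.000598 (0.154 by fry) and adjusted p = 0.592 with an estimated correlation. Rrm2 and Ccnb1 rose by 1.23 ± 0.22 and 1.10 ± 0.25. Of 22 cholesterol synthesis genes tested, 7 rose and 1 fell (Dhcr7), against 12 and 1 over the list alone. The cholesterol synthesis list had a median of 0.43, with camera adjusted p = 0.00139 (0.0557 by fry) and adjusted p = 0.481 with an estimated correlation. Pmvk rose by 0.66 ± 0.13. Of the bile acid genes, Slc10a2 went from 369 ± 64.7 CPM in BM to 866 ± 314 CPM in BMT (1.23 ± 0.26, adjusted p = 0.0056), while Fabp6 fell by 1.48 ± 0.38 (adjusted p = 0.0166, but 0.0669 without BM replicate 1, 6.4e-05 to 0.0669 over its filtered alternatives). Fgf15, the ileal hormone that represses hepatic bile acid synthesis, stood at 68.7 ± 38.9 CPM in BM and 19.6 ± 18.1 CPM in BMT (-1.81 ± 0.72, adjusted p = 0.0939), or -2.74 with adjusted p = 0.0268 without BMT replicate 3, adjusted p = 0.0484 with limma-voom and adjusted p = 0.0293 with the replicate block (adjusted p 0.0268 to 0.252 over its filtered alternatives). No call was made for Slc51b (0.44 ± 0.19, adjusted p = 0.115), Nr1h4 (0.25 ± 0.17, adjusted p = 0.319) or Slc51a (-0.27 ± 0.20, adjusted p = 0.364), the last passing without BMT replicate 3 (adjusted p = 0.0321, 0.0321 to 0.667 over its filtered alternatives). Gpbar1 was below the count filter.

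The remaining lists gave no call in these libraries. Bile acid synthesis genes gave no list call (median -0.29, adjusted p = 0.0644, but 0.0171 without BMT replicate 3). Of 9 tested, 0 rose and 3 fell (Cyp39a1, Hsd17b4, Slc27a2) (0 and 4 over the list alone). Bile acid transport genes gave no list call (median -0.14, adjusted p = 0.437). Of 10 tested, 1 rose (Slc10a2) and 4 fell (Fabp6, Abcc3, Abcg5, Abcg8) (1 and 4 over the list alone). Bile acid sensing genes gave no list call (median -0.17, adjusted p = 0.198, and 0.0405 by fry). Of 14 tested, 0 rose and 1 fell (Klb) (0 and 1 over the list alone). PPAR alpha and fatty acid oxidation genes gave no list call (median 0.11, adjusted p = 0.746). Of 18 tested, 3 rose (Acadl, Pdk4, Creb3l3) and 2 fell (Acaa1b, Acaa2) (4 and 2 over the list alone). Leukocyte chemokine genes gave no list call (median -0.78, adjusted p = 0.0554, but 0.0498 with the replicate block, 0.0454 without BM replicate 2 and 0.0168 without BM replicate 3, and 0.0374 by fry). Of 8 tested, 0 rose and 4 fell (Ccl9, Ccl20, Ccl28, Cxcl13) (0 and 5 over the list alone). B and plasma cell genes gave no list call (median 0.02, mean -0.91, adjusted p = 0.589, unlike the test's direction, lower). Of 5 tested, 1 rose (Ighm) and 2 fell (Igkc, Igha) (1 and 2 over the list alone). Monocyte and macrophage genes gave no list call (median 0.40, adjusted p = 0.0981, but 0.0142 without BM replicate 1). Of 12 tested, 3 rose (among them Ccr2, Ly6c2) and 1 fell (Itgam) (3 and 1 over the list alone). Neutrophil genes gave no list call (median 1.25, adjusted p = 0.139, but 0.0317 with the replicate block and 0.0355 without BM replicate 1). Of 5 tested, 2 rose (Ly6g, Ltf) and 0 fell (2 and 0 over the list alone). Endothelial genes gave no list call (median 0.14, mean -0.02, adjusted p = 0.955, unlike the test's direction, lower). Of 5 tested, 1 rose (Pecam1) and 1 fell (Esam) (1 and 1 over the list alone). Fibroblast and stellate cell genes gave no list call (median -0.19, adjusted p = 0.437, but 0.00596 without a low-count filter and 0.0336 without BMT replicate 3). Of 8 tested, 0 rose and 0 fell (0 and 0 over the list alone). P53 target genes gave no list call (median 0.05, mean -0.11, adjusted p = 0.699, unlike the test's direction, lower). Of 20 tested, 2 rose (Cdkn1a, Gtse1) and 2 fell (Phlda3, Btg2) (2 and 2 over the list alone). Unfolded protein response genes gave no list call (median 0.27, adjusted p = 0.265). Of 20 tested, 3 rose (Creld2, Trib3, Asns) and 2 fell (Atf3, Xbp1) (6 and 3 over the list alone). Hepatocyte marker genes gave no list call (median 0.80, adjusted p = 0.955, unlike the test's direction, lower). Of 11 tested, 3 rose (Apoa1, Pck1, Ass1) and 5 fell (Ttr, Tat, Cps1, Otc, Hpd) (5 and 5 over the list alone). Epithelial defence genes gave no list call (median -0.90, adjusted p = 0.109, but 0.0135 without BMT replicate 3). Of 17 tested, 3 rose (Duoxa2, Tnfaip3, Sprr2a3) and 6 fell (3 and 6 over the list alone). Regenerative epithelium genes gave no list call (median 0.65, adjusted p = 0.159, but 0.0146 without a low-count filter and 0.0408 without BM replicate 1). Of 14 tested, 5 rose (Ly6a, Il33, Ly6d, Areg, Ereg) and 2 fell (Ccn1, Mal) (7 and 2 over the list alone). Tight junction and adhesion genes gave no list call (median -0.01, adjusted p = 0.596). Of 19 tested, 1 rose (Cdh17) and 1 fell (Cldn8) (1 and 1 over the list alone).

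For the libraries titled large intestine, of 14621 genes tested, 1700 were higher and 1720 lower in BMT (994 and 1040 by at least 2-fold), and 10 of 31 lists were higher and 5 lower. Without BM replicate 2 there were 1030 higher and 1056 lower genes, without BM replicate 1 there were 1121 lower genes, and without BMT replicate 3 there were 9 lower lists. BMT replicate 2, the only library of the set on lane L001, left 1715 higher and 1512 lower genes when it was left out. BMT replicate 3 held liver transcripts (albumin, Alb, at 94.8 CPM against at most 1.16 CPM in the other 5), which bears on the hepatocyte genes above, and without it 1913 genes were higher and 1862 lower. Mitochondrial transcripts took 7.3 to 8.63% of counts in BM and 4.83 to 6.01% in BMT libraries.

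**Figure D2:**
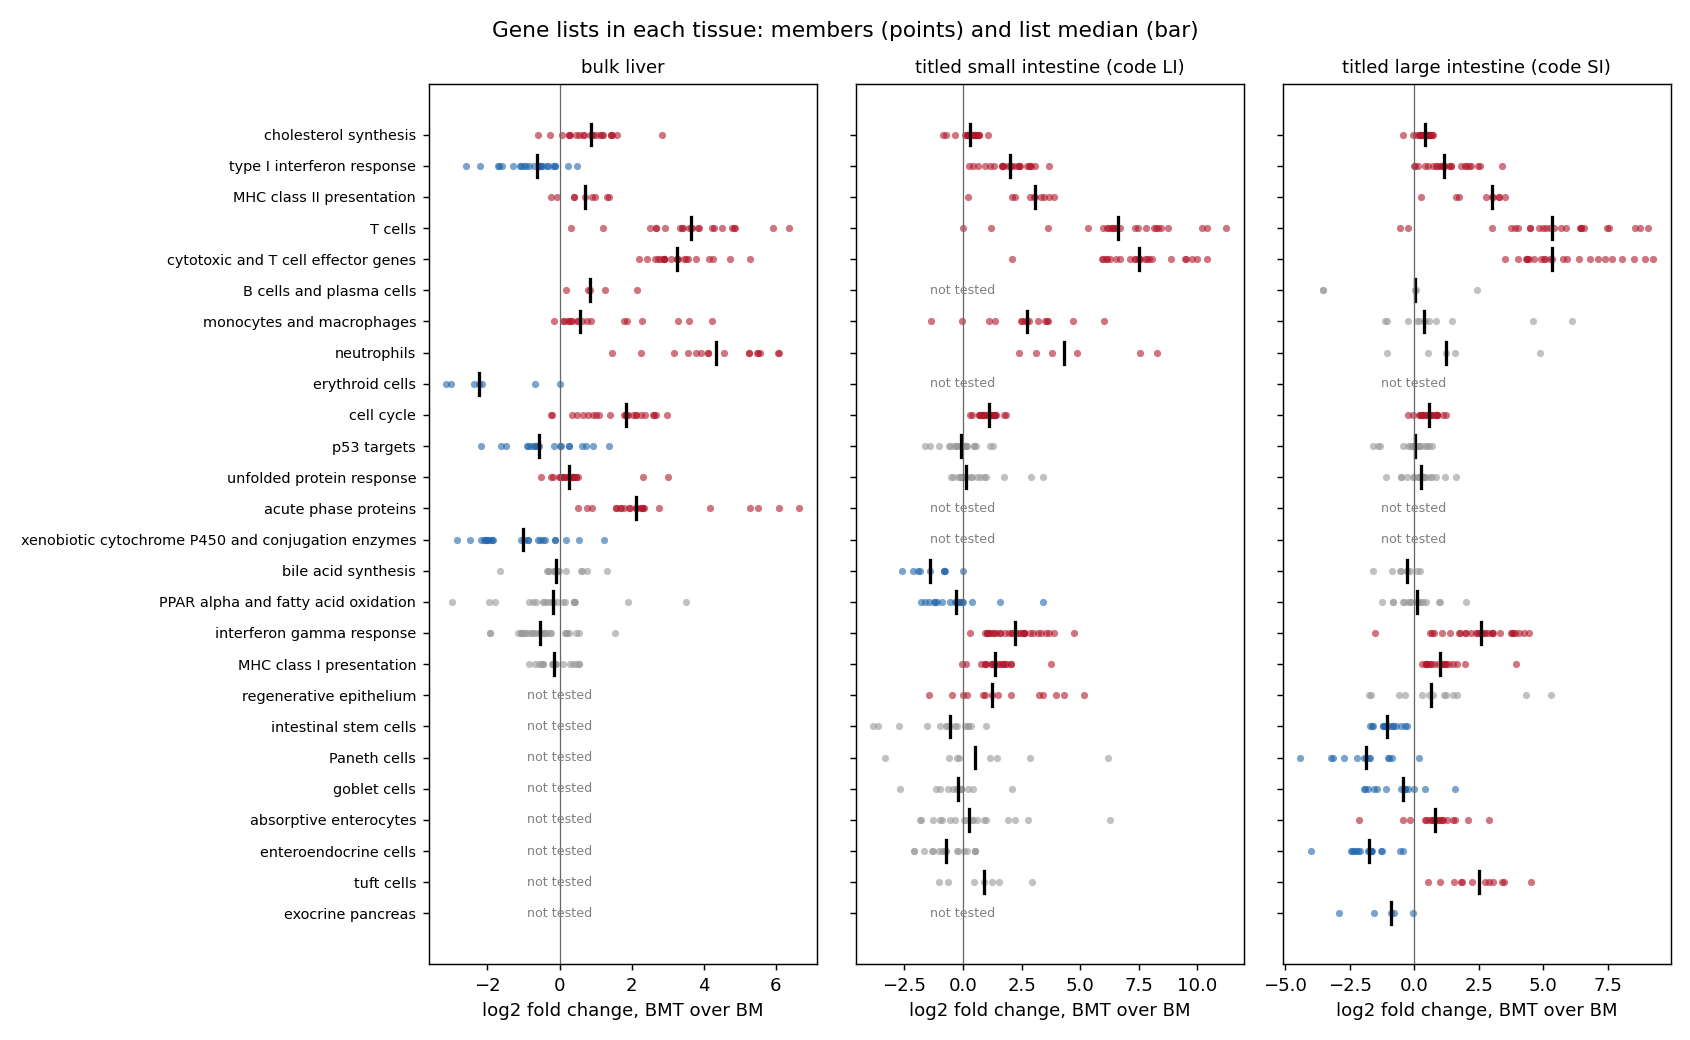
Log2 fold change, BMT over BM (x axes, with their own range in each panel), of the tested members (points) of each gene list called in at least 1 tissue, with the list median as a black bar. Red lists were higher and blue lists lower by camera, and grey lists were not called. T cell genes had medians of 3.66, 6.61 and 5.34 in liver, in libraries titled small intestine and in libraries titled large intestine.

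**Figure D3:**
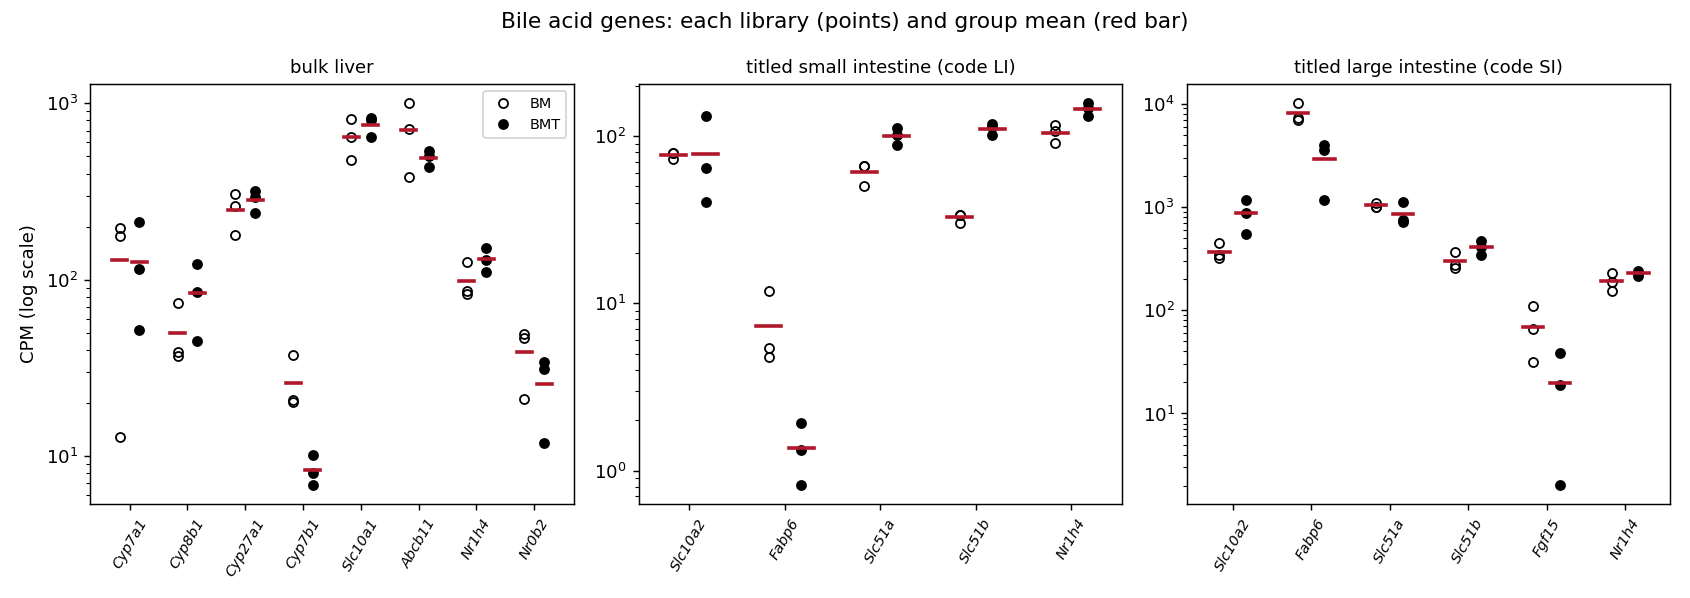
CPM on a log scale (y axes) of the bile acid genes of each tissue in BM (open points) and BMT libraries (filled points), 3 libraries per group, with the group mean as a red bar. Slc51b in libraries titled small intestine rose without overlap, while the BM and BMT points of Cyp7a1 in liver overlap.

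Whether the BMT effect differed between tissues was tested as the tissue by treatment term with the mouse as a block, over 17275 genes. Liver and the libraries titled small intestine differed in 3242 genes, liver and the libraries titled large intestine in 2588, and both intestinal sets in 848, of which 2843, 2250 and 793 were above the count filter in both tissues. Liver was bulk tissue and the intestinal sets epithelial fractions, so contrasts with liver cannot separate tissue from preparation. Between liver and titled small intestine, Ifitm1, an interferon-induced membrane gene, had log2 fold changes of 0.52 and 7.14. The membrane-binding gene Anxa6 had -0.20 and 4.19. Cyp4b1 went the other way (0.21 and -8.04), as did the cytochrome b561 gene Cyb561 (3.19 and -0.28). Between liver and titled large intestine, Cyb561 (3.19 and -0.24), the potassium channel gene Kcnn4 (2.83 and -0.86), Nrbp2 (1.27 and -1.94) and the chemokine gene Ccl6 (3.46 and -2.10) had the smallest p. Between titled small and titled large intestine, Cyp4b1 (-8.04 and 0.67) and Hoga1 (-2.70 and 0.77) had lower fold changes in the former. So had Mpp6 (-2.71 and 0.28) and the pore-forming gene Gsdme (-2.32 and -0.09). Of genes tested in both intestinal sets (14006), 1174 were higher and 1010 lower in both, where independent lists would share 332 and 319.6, and the sets come from the same mice. Mouse 4 and mouse 6 weighed on these counts, which were 1844 and 1957 (liver and titled small), 1144 and 1410 (liver and titled large) and 297 and 363 (both intestinal sets) without them, and the last was 455 without mouse 2 and 485 without mouse 5.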

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

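The tests of lists between tissues, of exchanged titles or codes and mixed regions, of dilution and fewer crypts, and of other splits were chosen after the results were seen, unlike the planned tests of genes between tissues and the test of liver carry-over. By a test of the difference, the BMT effect differed in 3242 (liver, titled small), 2588 (liver, titled large) and 848 genes (both intestinal sets). Contrasts with liver cannot separate tissue from preparation (bulk against epithelial fractions). As second minus first tissue on the log2 scale, liver against titled small intestine differed in Ifitm1 (6.62 ± 0.37, adjusted p = 3.96e-07), Cyp4b1 (-8.29 ± 0.51, adjusted p = 7.44e-07), Anxa6 (4.34 ± 0.28, adjusted p = 1.08e-06), Cyb561 (-3.51 ± 0.23, adjusted p = 1.12e-06), Rsad2 (4.55 ± 0.51, adjusted p = 3.12e-05) and Thy1 (4.07 ± 0.39, adjusted p = 9.09e-06). Liver against titled large intestine differed in Cyb561 (-3.44 ± 0.23, adjusted p = 5.09e-06), Kcnn4 (-3.70 ± 0.27, adjusted p = 5.09e-06), Nrbp2 (-3.20 ± 0.23, adjusted p = 5.09e-06), Ccl6 (-5.75 ± 0.43, adjusted p = 5.27e-06) and Thy1 (3.80 ± 0.42, adjusted p = 6.74e-05). Titled small against titled large intestine differed in Cyp4b1 (8.73 ± 0.50, adjusted p = 5.29e-07), Hoga1 (3.50 ± 0.28, adjusted p = 2.97e-05), Mpp6 (3.04 ± 0.25, adjusted p = 2.97e-05), Gsdme (2.26 ± 0.21, adjusted p = 7.81e-05) and the bile acid exporter genes Slc51a (-1.001 ± 0.24, adjusted p = 0.0425) and Slc51b (-1.30 ± 0.28, adjusted p = 0.0169).

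Whole lists differed too (median log2 differences over members above the count filter in both tissues, at least 5 needed). More positive in titled small intestine than in liver were interferon gamma response (1.96), type I interferon response (2.58), MHC class I presentation (1.50), T cells (2.83), cytotoxic and T cell effector genes (4.19) and monocytes and macrophages (1.53), and less positive were bile acid synthesis (-1.16) and cholesterol synthesis (-0.62) (camera adjusted p = 2.02e-14 to 0.0197). In titled large intestine against liver, more positive were interferon gamma response (2.94), type I interferon response (1.89), MHC class I presentation (1.00), T cells (1.82) and cytotoxic and T cell effector genes (2.19), and less positive cholesterol synthesis (-0.44), neutrophils (-3.48) and cell cycle (-0.97) (adjusted p = 1.33e-10 to 0.0237). Going from titled small to titled large intestine, bile acid synthesis (0.95), PPAR alpha and fatty acid oxidation (0.46), absorptive enterocytes (0.76) and tuft cells (2.94) were more positive and type I interferon response (-0.59), T cells (-1.40), cytotoxic and T cell effector genes (-1.57), T cell and leukocyte chemokines (-0.81), monocytes and macrophages (-2.18), neutrophils (-3.11), cell cycle (-0.49), Paneth cells (-1.92) and enteroendocrine cells (-1.13) less positive (adjusted p = 7.9e-07 to 0.0376). With an estimated correlation no list difference passed, the smallest adjusted p being 0.297, 0.3 and 0.211. Hepatocyte markers did not pass between the intestinal sets (adjusted p = 0.0798, and 0.0878 without mouse 10, whose library titled large intestine held liver transcripts).

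Region markers ran against the titles of both intestinal sets. In each of 6 mice the score was negative, the highest being -8.57, so an exchange of the titles between the sets may account for it, with both sets out of place. A mixture of both regions in each set would need scores near 0 and is argued against by the mean of -9.48 ± 0.64. An exchange of the library codes is argued against: the small intestine list exceeded the large intestine list by 5.73 to 6.81 in all 6 libraries with code SI, while in all 6 with code LI the difference was -3.79 to -1.91. Each title goes with a single code, so these are the same scores read by code and not separate evidence. At which step the titles came to differ stays open, and no biological explanation was tested.

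Paneth, stem and enteroendocrine genes fell together in the libraries titled large intestine (code SI), with a median of -1.63 over 45 genes, 36 of them called lower, but none of the 3 lists held its call with an estimated correlation (adjusted p = 0.223 to 0.475). Dilution of epithelial RNA by leukocyte RNA would lower general epithelial genes alike, but 13 of these had a median of 0.051 ± 0.43 (SD). Fewer crypts in the collected epithelium cannot be told apart from loss within crypts: the cell cycle list, which crypt loss would lower, had a median of 0.58, but T cell genes rose in the same libraries and leukocytes may bring cell cycle transcripts. An effect of the T cells on these epithelial cells stays open and untested.

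Albumin (Alb) stood at 94.8 CPM in BMT replicate 3 titled large intestine (code SI) and at most at 1.16 CPM in the other 5 libraries of that set. Of 49 other abundant liver genes with a mean of at most 2 CPM in those 5, 42 (85.7%) were within 3-fold of the ratio of Alb, which was 0.0917% of its liver level, but in 6 of the 49, 4 of them among the 42, another library held more. Of the 29 at or below 0.3 CPM in each of the other 5, a limit chosen after seeing the data, 25 (86.2%) were within 3-fold. A carry-over of liver RNA or reads into this library is a candidate explanation. No biological explanation was tested.

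The 6 libraries of a tissue, or the 6 mice, can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only the real split gave edgeR calls, in each gene count and each contrast. Every other split mixes BM and BMT in both groups, which can widen their spread, so its 0 calls do not measure chance. At an unadjusted p under 0.05 the real split gave 3705, 7390 and 5245 genes per tissue and 5540, 5161 and 3541 per contrast. Other splits gave at most 1415, 711 and 886, and 824, 1124 and 998. Lists did not separate the real split: as many higher lists in one direction came in 3, 2 and 3 of 10 splits and as many lower lists in 10, 10 and 9 of 10 (liver, titled small, titled large), with real counts of 10 and 4, 11 and 2, and 10 and 5, and at most 11, 11 and 10 in another split.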

How the results depend on the processing

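Lane as a covariate, lane L002 alone and the settings of list differences between tissues were chosen after the data were seen. Among lists compared both ways, members above the filter in any 1 tissue gave 4 more list differences and lost 1 (absorptive enterocytes between the intestinal sets, adjusted p = 0.0765). B and plasma cells (liver against titled large intestine, adjusted p = 0.041, and both intestinal sets, 0.00181) and erythroid cells (both intestinal sets, 0.0299) also passed that way, with too few members above the filter in both tissues to compare. Apart from a 2-fold threshold, counts in titled small intestine stayed within 2244 to 3783 higher and 2274 to 3553 lower genes in all alternatives. A stricter filter, which tests fewer genes, gave 538 higher and 303 lower genes in liver and 1011 and 1099 in libraries titled large intestine, and DESeq2 gave 768 lower genes in liver. A 2-fold threshold left 197 lower genes in liver, 1592 and 1515 in titled small and 994 and 1040 in titled large intestine, by construction. Leaving out 1 library gave 459 to 1556 higher and 110 to 1061 lower genes in liver, 1030 to 1913 and 1056 to 1862 in titled large intestine. Leaving out 1 mouse gave 1844 to 3165, 1144 to 2504 and 297 to 1121 genes in the contrasts, and identity scores of -9.66 to -9.34, where 5 mice allow no p under 0.0625. Fewer samples can lower such counts, and the cause of the rise in liver without BM replicate 3 was not tested. DESeq2 size factors moved the median log2 fold change by at most 0.0174.

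With an estimated correlation 0 lists were called higher or lower in any tissue, where the estimate replaces the preset correlation of 0.01. Single-gene p-values without a low-count filter carry little weight, since the spread of single genes was there partly (liver) or wholly (intestinal sets) pooled (Fgf15 in titled large intestine, adjusted p = 7.58e-19 against 0.0939). Fry, which tests a list against no change and not against other genes as camera does, called 1 lower list in liver and 6 in titled small intestine. Camera without a low-count filter called 4 there, and the cause was not tested. Leaving out 1 library gave 2 to 4 lower lists in titled small and 5 to 9 in titled large intestine.

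Among named genes, only those without a call in the main comparison changed sign. Cyp7a1 in liver turned positive with the stricter filter (0.0284), limma-voom (0.51), 1 fit of all libraries (0.0218), the replicate block (0.46), lane as a covariate (0.022) and lane L002 alone (0.34), and ran from -0.62 to 0.42 leaving out 1 library. Cyp27a1 was -0.0365 on lane L002 alone and -0.0117 to 0.35 leaving out 1 library. Slc10a2 in titled small intestine was -0.14 with limma-voom, -0.14 with the replicate block and -0.55 to 0.35 leaving out 1 library. Slc10a2 passed without BMT replicate 1, and the cause was not tested.

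Lists that turned direction had no call in the main comparison. Their adjusted p after turning was, for bile acid synthesis in liver 0.903 (no low-count filter), MHC class I presentation in liver 0.997 (fry), hepatocyte markers in liver 0.95 (no low-count filter), bile acid transport in titled small 0.159 (fry), epithelial defence in titled small 0.946 (fry), tight junction and adhesion in titled small 0.996 (DESeq2 size factors), 0.812 (no low-count filter), 0.988 (replicate block) and hepatocyte markers in titled large 0.238 (no low-count filter), 0.826 (replicate block). Leaving out 1 library also turned some, over adjusted p ranges of, for bile acid synthesis in liver 0.276 to 0.903, interferon gamma response in liver 6.77e-05 to 0.939, MHC class I presentation in liver 0.00585 to 0.992, hepatocyte markers in liver 0.51 to 0.872, epithelial defence in titled small 0.371 to 0.994, tight junction and adhesion in titled small 0.794 to 0.998, PPAR alpha and fatty acid oxidation in titled large 0.336 to 0.923, B cells and plasma cells in titled large 0.288 to 0.981, endothelial cells in titled large 0.672 to 0.944, p53 targets in titled large 0.625 to 0.926 and hepatocyte markers in titled large 0.634 to 0.918. Of these the interferon gamma list in liver passed in opposite directions without BM replicate 3 and without BM replicate 1. The cause was not tested.

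Title numbers name different mice in BM and BMT and are not used to pair them: deviations of same-numbered libraries correlated at -0.04 to 0.34 in liver, -0.15 to 0.06 in titled small and -0.07 to 0.08 in titled large intestine, and 2, 1 and 1 of 3 correlated best with their own number. The replicate block gave 1125 higher and 505 lower genes, 2637 and 2730, and 1500 and 1528. With 18845483 counts in the smallest library, genes near 0.159 CPM are at the floor.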

Other observations

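The genes here were chosen after their values were seen, outside the naming rule. The nitric oxide synthase gene Nos2 was the 1 interferon gamma gene that fell in libraries titled large intestine (code SI), from 164 ± 17 to 58 ± 6.61 CPM (-1.50 ± 0.15, adjusted p = 6.33e-05, edgeR). It rose in those titled small intestine (code LI) (2.61 ± 0.35, adjusted p = 0.000187), and the effects differed (titled large minus small -4.03 ± 0.47, adjusted p = 0.000178). Apoa4, a lipoprotein gene, rose in titled large (2.91 ± 0.39, adjusted p = 0.000414) and titled small intestine (6.25 ± 0.96, adjusted p = 0.000481, lowest library below the floor at 0.0509 CPM). In liver, S100a8 and S100a9 of neutrophils rose by 4.11 ± 0.60 and 4.11 ± 0.61, and haptoglobin (Hp) by 2.31 ± 0.39.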
